A study of Rattus norvegicus with 6 samples.

How the data were processed

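RNA from neurospheres of adult rat carotid body cells was measured on 6 Affymetrix arrays, 3 labelled undifferentiated and 3 labelled differentiated, with biotin-labelled cRNA made from 100 ng of total RNA per the labels' protocols. The deposited table holds 1 value per probe set and array for 29214 probe sets. The values are on a log2 scale, as the authors deposited them; the base was inferred here from their range and is not stated in the labels. The background correction, normalization, summarization and software behind the values are not given in the sources used here. Array minima lay between 0.42 and 0.74, medians between 5.05 and 5.13 and maxima between 13.77 and 14.09, and the values were used as deposited, with no further normalization. How far dim probe sets stood over background is not known here.

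Probe sets were named from the platform's probe table. Of the 29214 probe sets, 15633 were listed there, 15310 with exactly 1 gene symbol and 323 with several, and 13581 were not listed and are unnamed here. Of the single-gene probe sets, 99.8% were matched by gene ID to the rat gene table of the GRCr8 assembly, which changed 0 symbols; no coordinates from it are given, since the build behind the array's design is not given in the sources used here. Each gene was represented by its probe set with the highest mean over the 6 arrays, which left 14506 genes, 527 of them with over 1 probe set. No gene had probe sets past the threshold in both directions, and 319 probe sets had values identical to those of another probe set on all 6 arrays. Genes of large families can share probes with near-identical copies and are less certain.

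Groups and replicate numbers were taken from the sample titles. The labels do not say whether the arrays of a group came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. All 6 arrays entered a single fit of limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), labelled differentiated minus labelled undifferentiated, with no block, a two-sided moderated test and Benjamini-Hochberg adjustment over all genes at 0.05. The median residual SD was 0.16 and the median of all log2 fold changes 0.06. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

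The design, the 24 gene lists, the naming rule and the alternatives were fixed before the data were examined, apart from an alternative on older symbols described with the closing results. The lists cover glomus cells and catecholamines, carotid body oxygen sensing, neuronal cytoskeleton and axon, synaptic vesicles and exocytosis, glia and Schwann lineage, neural crest and mesenchymal progenitors, smooth muscle and pericytes, fibroblasts and collagen matrix, endothelial cells, macrophages and leukocytes, erythroid cells and adipocytes, cartilage and bone, mitosis, DNA replication, hypoxia response, glycolysis, oxidative phosphorylation, growth factor and ERK feedback, FoxO and growth factor withdrawal, cholesterol synthesis, integrated and endoplasmic reticulum stress, p53 response, interferon response, and neuropeptides and transmitter receptors. Members were matched by symbol, older symbols through the gene table's synonyms, the FoxO list shared 4 members and the hypoxia list 3 with other lists (no other list over 1), and members with no single-gene probe set were not analysed here. Each list was tested with limma's camera with a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 24 lists. This test compares a list with all other genes. Of the 16 lists called, 2 were called with an estimated correlation. Fry, which tests whether a list's genes move on balance in a single direction and compares them with no other genes, and camera on ranks were alternatives.

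The genes named are the 12 with the largest rise and the 12 with the largest fall among changed genes whose groups did not overlap, and up to 4 members of each list. From each list these were the 2 with the smallest p in the direction of the list's median and the 2 with the smallest p that passed in the other direction; with none past the threshold, the 2 with the smallest p. Th, Tubb3, Gfap, Nes and Mki67 were named in any case as checks of the labels. Symbols of clone type were to be counted in place of being named, and 0 of them were among the largest changes. In the erythroid and adipocyte list, Hbb-b1 and Plin1 were named under the rule although they did not pass.

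The alternatives were the replicate number as a block, quantile normalization, median centring, leaving out genes at or below the 40th percentile of probe set means, the mean of a gene's probe sets or the probe set of largest variance, leaving out each array in turn, eBayes without the trend or robust, array weights, an unmoderated test, stricter thresholds and all probe sets. The planned comparison of 3' with 5' control probe sets for RNA quality was not made and control probe sets were not removed from the alternative on all probe sets, because controls were not named in the table used here. The fits were tested on simulated data with 200 of 14506 genes changed, for 3 arrays labelled differentiated against 3 labelled undifferentiated. They recovered 26% of genes changed by 0.5 on the log2 scale, 86% of those changed by 1, 98% by 2 and 100% by 3, with 4.91% of calls false, and called 0 of 20 unshifted lists. The simulated genes varied independently, whereas the estimated correlation within the real macrophage list was 0.639. The simulation therefore does not show how the list calls fare with correlated genes. Its share of changed genes was also far below the 29.6% called in the arrays.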

Results

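Neurospheres are floating cell clusters, grown here from dispersed cells of the adult rat carotid body, the oxygen-sensing organ at the fork of the carotid artery. Total RNA from them was measured on 6 Affymetrix arrays, 3 labelled undifferentiated and 3 labelled differentiated. Per the labels, the cultures ran for 10 days, the undifferentiated spheres with mitogens in normal oxygen and the differentiated spheres without mitogens at 3% oxygen. The mitogens and the oxygen level therefore changed together. The question stated for the series was which molecular pathways set neuron-rich spheres apart from spheres rich in undifferentiated cells. Array medians lay between 5.05 and 5.13 on the log2 scale, and 14506 genes were tested. Pearson correlations over all probe sets were 0.9857 to 0.9927 within the groups and 0.959 to 0.9696 between them, and the first principal component, with 76.7% of the variance, separated the groups.

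In the arrays labelled differentiated, transcripts of glomus cells, the oxygen-sensing and catecholamine-making cells of the carotid body, were lower, as were transcripts of synaptic vesicle proteins and of the hypoxia response. Transcripts of collagen matrix, of mesenchymal progenitors, of cell division and of the feedback on growth factor signalling were higher there. With an estimated correlation only the calls of the glomus and synaptic vesicle lists held (adjusted p = 0.0434 each). It gave adjusted p = 0.215 for hypoxia, 0.156 for collagen matrix, 0.189 for progenitors, 0.189 for mitosis, 0.202 for DNA replication and 0.156 for growth factor feedback. Th, the rate-limiting enzyme of catecholamine synthesis and a check of the labels, had a mean log2 value of 10.90 ± 0.37 (SD, n = 3) in the arrays labelled differentiated and 13.76 ± 0.16 (SD, n = 3) in those labelled undifferentiated. It fell by 2.86 ± 0.18 (SE), a 7.24-fold difference (limma adjusted p = 5.09e-07). This goes against the labels, so the groups are named by their labels throughout, and every direction below is that of the arrays labelled differentiated against those labelled undifferentiated.

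The other label checks did not pass in the fit of all 6 arrays. Tubb3, a neuronal tubulin, differed by -0.00165 ± 0.12 (SE, limma adjusted p = 0.995), and Gfap, a glial filament protein, by 0.19 ± 0.14 (adjusted p = 0.373). When each array was left out, the difference ran from -0.07 to 0.12 for Tubb3 and from 0.10 to 0.32 for Gfap. Nes, a filament protein of neural progenitors, differed by 0.65 ± 0.23 (adjusted p = 0.0542). Nes passed with quantile normalization (adjusted p = 0.0366), with dim genes left out (adjusted p = 0.048), without undifferentiated replicate 1 (0.82, adjusted p = 0.0311) and without differentiated replicate 2 (0.88, adjusted p = 0.00812), and its difference was 0.39 without undifferentiated replicate 2. Nes also passed with the replicate number as a block (limma adjusted p = 0.000308), though the labels do not say that these numbers pair the arrays. Mki67, the proliferation marker Ki-67, was not analysed here.

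Of the 14506 genes, 4286 (29.6%) changed at a limma adjusted p under 0.05, 2128 higher and 2158 lower in the arrays labelled differentiated. In 4223 of the changed genes the 3 arrays of a group all lay above the 3 of the other; 42.3% of all genes had such groups, against 10% by chance. Falls were larger than rises: a log2 change of at least 1 was reached by 464 genes that rose and 696 that fell, and a change of at least 2 by 40 and 197. An equal-variance two-sample test without moderation called 2740 genes. Of the genes named by rule that limma called, Tnn, Cth, Elavl2, Itga6, Egr2, Eng, Egfl7, Cd14, Tyrobp, Fabp4, Alpl, Hk2, Ndufs1, Txnip, Trib1 and Psmb9 were not called by that test.

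**Figure D1:**
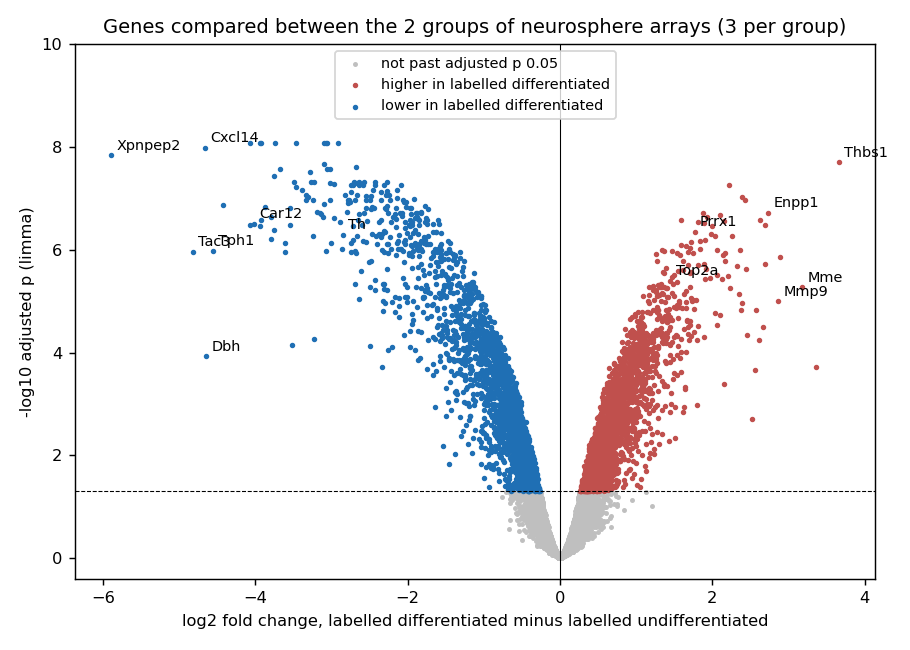
Log2 fold change of each of the 14506 genes (horizontal axis, labelled differentiated minus labelled undifferentiated, n = 3 arrays each) against the negative log10 of its limma adjusted p (vertical axis). The 2128 genes that rose are red, the 2158 that fell are blue, the others are grey, and the dashed line marks an adjusted p of 0.05; Xpnpep2 lies at the far left, at -5.89, and Thbs1 at the far right, at 3.66.

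The largest rises included secreted and matrix-related genes. Thbs1, thrombospondin of the extracellular matrix, rose by 3.66 ± 0.13 (SE, limma adjusted p = 1.97e-08), from a mean of 7.90 to 11.56. Tnn, a tenascin, rose by 3.36 ± 0.45 and Mme, the cell-surface peptidase neprilysin, by 3.18 ± 0.26. The matrix metalloproteinases Mmp9 and Mmp13 rose by 2.87 and 2.62, and Tfpi2, a secreted protease inhibitor, by 2.57. The interleukin-33 receptor Il1rl1 rose by 2.88, the ectonucleotide pyrophosphatase Enpp1 by 2.73, the aryl hydrocarbon receptor Ahr by 2.69, Lmcd1 by 2.69, the actin-severing protein Scin by 2.67 and Clec2dl1, from a dim mean of 3.54, by 2.61. The adjusted p of these 12 genes was at most 0.000189.

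The largest falls included genes of amine and peptide transmission. Xpnpep2, a membrane aminopeptidase, fell by 5.89 ± 0.20 (SE, limma adjusted p = 1.47e-08). Its arrays labelled differentiated read 3.17, 2.73 and 3.10, below their lower quartiles of 3.44, 3.52 and 3.48, and were not shown to lie above background, so the size of this fall is uncertain. Tac3, the precursor of neurokinin B, fell by 4.82 ± 0.33, the chemokine Cxcl14 by 4.66 ± 0.15, and Tph1, the rate-limiting enzyme of serotonin synthesis in peripheral tissues, by 4.56 ± 0.31. Dbh, which makes noradrenaline, fell by 4.65 ± 0.59 (adjusted p = 0.000118). Its 3 arrays labelled differentiated were spread widely, at 5.79, 9.03 and 7.04, and all lay below the lowest array labelled undifferentiated, at 11.74. Tmem255b fell by 4.43. Fetub fell by 4.07, as did Gpr155. The carbonic anhydrase Car12 fell by 4.02, Tmem130 by 3.94, the lipocalin Lcn2 by 3.93 and the neurexophilin Nxph4 by 3.93. The adjusted p of all 12 genes was at most 0.000118.

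Of 22 measured genes of the glomus cell and catecholamine list, 0 rose, 18 fell and 4 did not pass, with the same counts adjusted over the list alone. The median change was -2.40 (camera adjusted p = 2.72e-14 over the 24 lists), and the adjusted p = 0.0434 with an estimated correlation. Ddc, which makes dopamine, fell by 3.25, and Gch1, which makes the cofactor of tyrosine hydroxylase, by 3.23. The 4 that did not pass were Pcsk2 (0.03), Slc6a2 (0.10), Gata2 (0.19) and Gfra1 (0.45), named after their values were seen. The synaptic vesicle and exocytosis list moved the same way: of 23 measured genes 1 rose and 17 fell, 18 of them adjusted over the list alone (median -1.19, camera adjusted p = 3.38e-12, adjusted p = 0.0434 with an estimated correlation). The vesicle protein Sv2c fell by 3.46 and the calcium sensor Syt4 by 2.76, while Sypl1, a vesicle protein also made outside neurons, rose by 0.45. Both calls held with an estimated correlation, which no other called list did.

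Among 19 measured genes of the carotid body oxygen sensing list, 2 rose and 11 fell, with the same counts adjusted over the list alone (median -1.25, camera adjusted p = 3.52e-06). The adjusted p = 0.116 with an estimated correlation, and the median was -1.98 where dim genes were left out. Cox4i2, the cytochrome oxidase subunit known from oxygen-sensing cells, fell by 3.50 ± 0.14 (SE), and Pc, pyruvate carboxylase, fell by 2.91 ± 0.09. Hif1a, a hypoxia-inducible factor, rose by 1.72 ± 0.11 and Cth, which makes hydrogen sulfide, by 0.62 (adjusted p = 0.013). Epas1, another hypoxia-inducible factor, fell by 2.45 (limma adjusted p = 1.5e-07) and was named after its value was seen. Cth lost its call without undifferentiated replicate 2 (adjusted p = 0.0527) and without differentiated replicate 3 (adjusted p = 0.0572).

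The neuronal cytoskeleton and axon list was divided. Of 23 measured genes 3 rose and 9 fell, 3 and 10 adjusted over the list alone, with a median of -0.11 (camera adjusted p = 0.0347). The call was lost with an estimated correlation (adjusted p = 0.337 with an estimated correlation), on ranks (adjusted p = 0.0592) and with dim genes left out (adjusted p = 0.123). It was also lost without undifferentiated replicate 1 (adjusted p = 0.0611, median -0.05) and without differentiated replicate 3 (adjusted p = 0.0806), and the median was -0.17 without undifferentiated replicate 2. The neurofilament-associated Ina fell by 2.04 and Crmp1, of the semaphorin response, by 1.31. The growth cone protein Gap43 rose by 0.65, the RNA-binding Elavl2 by 0.83 and the neurofilament Nefl by 1.21, the last named after its value was seen.

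**Figure D2:**
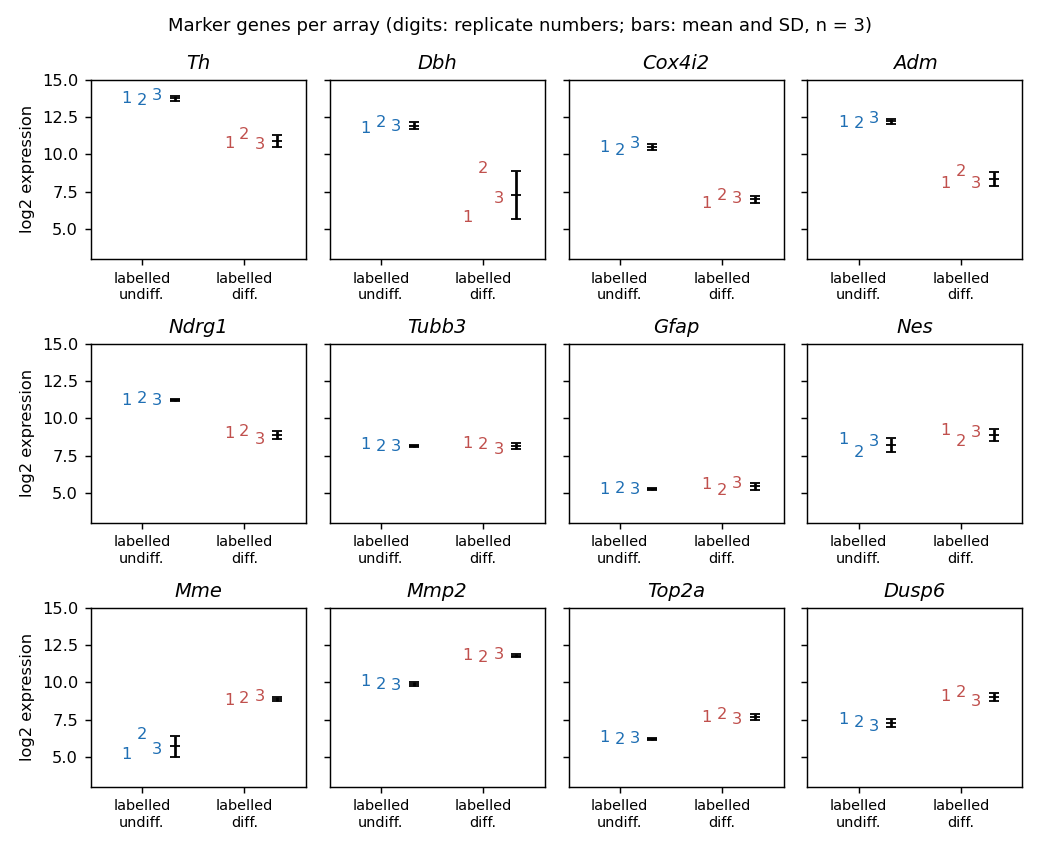
Log2 expression (vertical axis) of 12 genes on each array, with the digit giving the replicate number within the arrays labelled undifferentiated (blue) or differentiated (red) and the bars giving mean and SD (n = 3). Th, Dbh, Cox4i2, Adm and Ndrg1 lay lower and Mme, Mmp2, Top2a and Dusp6 higher on every array labelled differentiated, while the groups overlapped for Tubb3, Gfap and Nes.

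Matrix and mesenchymal lists rose. Of 19 measured fibroblast and collagen matrix genes 18 rose, 0 fell and 1, Fbln1 at -0.20, did not pass, with the same counts adjusted over the list alone (median 1.25, camera adjusted p = 9.26e-13, adjusted p = 0.156 with an estimated correlation). Loxl1, which cross-links elastin, rose by 1.91 and the gelatinase Mmp2 by 1.89. In the neural crest and mesenchymal progenitor list 16 of 22 measured genes rose and 3 fell, the same adjusted over the list alone (median 0.65, camera adjusted p = 2.34e-05, adjusted p = 0.189 with an estimated correlation). Besides Mme, the mesenchymal transcription factor Prrx1 rose by 1.77, while Id2, Id1 and Thy1 fell by 1.05, 0.84 and 0.77. Of 17 smooth muscle and pericyte genes 9 rose and 0 fell, 11 and 0 adjusted over the list alone (median 0.53, camera adjusted p = 8.53e-05, adjusted p = 0.0897 with an estimated correlation), among them the contractile genes Cald1 at 1.33 and Acta2 at 0.97. Of 17 cartilage and bone genes 8 rose and 1 fell, 9 and 1 adjusted over the list alone (median 0.39, camera adjusted p = 0.000839, adjusted p = 0.208 with an estimated correlation). The collagen Col11a1 rose by 1.41 and the proteoglycan Acan by 1.24. The phosphatase Alpl fell by 0.53, a call lost without undifferentiated replicate 1 (adjusted p = 0.0975) and without differentiated replicate 2 (adjusted p = 0.0686). Fbln1 and Id1 were named after their values were seen.

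The glial, endothelial, leukocyte and erythroid and adipocyte lists gave no call. In the glia and Schwann lineage list 4 of 20 measured genes rose and 1 fell, 7 and 1 adjusted over the list alone (median 0.28, camera adjusted p = 0.0966). That list passed on ranks (adjusted p = 0.0233), without differentiated replicate 2 (adjusted p = 0.00796) and with the replicate number as a block (camera adjusted p = 0.0271). The laminin receptor subunit Itga6 rose by 0.86, S100b by 0.74, Egr2 by 0.61 and Foxd3 by 0.35, and the myelin protein Mbp fell by 1.97. Egr2 lost its call without undifferentiated replicate 2 (adjusted p = 0.0827), undifferentiated replicate 3 (0.0716) and differentiated replicate 3 (0.0816). Of 17 endothelial genes 2 rose and 2 fell, the same adjusted over the list alone (median 0.06, camera adjusted p = 0.75). That median was -0.00726 with quantile normalization and 0.0151 to 0.162 when each array was left out. Erg rose by 0.96 and Eng by 0.80, the tight junction protein Cldn5 fell by 2.31 and Egfl7 by 0.50. Egfl7 lost its call without undifferentiated replicate 3 (adjusted p = 0.0752) and without differentiated replicate 2 (adjusted p = 0.0508). Among 22 macrophage and leukocyte genes 3 rose and 3 fell, the same adjusted over the list alone (median -0.05, camera adjusted p = 0.724). The sign of that median turned when single arrays were left out, with a range of -0.13 to 0.08. Cd74, the invariant chain of antigen presentation, fell by 2.64, Cybb by 1.27 and Cd163 by 1.00, and Tyrobp rose by 1.24, Cd14 by 0.68 and Spi1 by 0.58. In the erythroid and adipocyte list 0 of 12 measured genes rose and 1 fell, the same adjusted over the list alone. Its median was 0.01 (-0.05 to 0.06 when each array was left out, -0.02 with median centring) and its mean -0.09, and the test pointed down (camera adjusted p = 0.724). The fatty acid carrier Fabp4 fell by 0.78, and Hbb-b1 and Plin1 differed by 0.31 and 0.20 (0.11 to 0.44 and 0.09 to 0.33 when each array was left out). S100b, Foxd3, Cd163 and Spi1 were named after their values were seen.

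Cell division genes rose in the arrays labelled differentiated, the group without mitogens per the labels. Of 22 measured mitosis genes 19 rose and 0 fell, 20 and 1 adjusted over the list alone (median 1.12, camera adjusted p = 5.28e-10, adjusted p = 0.189 with an estimated correlation). Top2a, the topoisomerase of dividing cells, rose by 1.45 ± 0.12 (SE) and Prc1, of the central spindle, by 1.35 ± 0.10. The 3 that did not pass were Nuf2 (-0.28, the gene counted as falling within the list), Kif2c (-0.07) and Ube2c (0.26), named after their values were seen. Of 22 DNA replication genes 17 rose and 0 fell, 21 and 0 adjusted over the list alone (median 0.64, camera adjusted p = 1.67e-07, adjusted p = 0.202 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose by 1.76 and the helicase subunit Mcm6 by 1.02.

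Growth factor signalling genes moved with them. Of 24 growth factor and ERK feedback genes 17 rose and 1 fell, the same adjusted over the list alone (median 0.89, camera adjusted p = 1.11e-07, adjusted p = 0.156 with an estimated correlation). Dusp6, a phosphatase that switches off ERK, rose by 1.75 ± 0.16 (SE) and the immediate early gene Egr1 by 1.71 ± 0.14, while Etv5 fell by 0.71. Of 21 FoxO and growth factor withdrawal genes 3 rose and 9 fell, the same adjusted over the list alone (median -0.16, camera adjusted p = 0.00804, adjusted p = 0.156 with an estimated correlation). The median was -0.25 without undifferentiated replicate 1 and -0.24 without differentiated replicate 3. Igf1r, a receptor for insulin-like growth factors, fell by 1.40 and the antiproliferative Tob1 by 1.32. Txnip rose by 0.62, Trib1 by 0.65 and Bcl6, named after its value was seen, by 0.36. Txnip lost its call without undifferentiated replicates 1 (adjusted p = 0.0587), 2 (0.146) and 3 (0.0729), differentiated replicate 2 (0.0953, change 0.36) and differentiated replicate 3 (0.078), and with eBayes without the trend (0.0671). Trib1 lost its call without undifferentiated replicates 2 (adjusted p = 0.172) and 3 (0.131) and differentiated replicates 1 (0.155) and 3 (0.135). It also lost it with median centring (0.0639), eBayes without the trend (0.0666) and array weights (0.0514).

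Hypoxia response genes were lower in the arrays labelled differentiated, the group at 3% oxygen per the labels. Of 25 measured genes 2 rose and 16 fell, the same adjusted over the list alone (median -0.68, camera adjusted p = 4.04e-06, adjusted p = 0.215 with an estimated correlation). Adm, the vasodilator peptide adrenomedullin, fell by 3.88 ± 0.20 (SE), a 14.7-fold difference, and Ndrg1 fell by 2.35 ± 0.13. Lox and Plod2, which modify collagen, rose by 1.71 and 0.85. Of 17 glycolysis genes 1 rose and 9 fell, 1 and 10 adjusted over the list alone (median -0.54, camera adjusted p = 0.00022, adjusted p = 0.32 with an estimated correlation). Eno2, the neuronal enolase, fell by 2.09 and Pfkp by 1.70, and Hk2 rose by 0.65. Of 26 oxidative phosphorylation genes 5 rose and 2 fell, 3 and 2 adjusted over the list alone (median 0.15, camera adjusted p = 0.22, and 0.0444 with quantile normalization). The median ran from 0.09 to 0.22 when each array was left out. Ndufa4 rose by 0.52, Cox5a by 0.49, Cycs by 0.42, Uqcrfs1 by 0.35 and Ndufv1 by 0.29, the last 3 named after their values were seen, and Ndufa1 fell by 0.96. Ndufs1 fell by 0.34, a call lost without undifferentiated replicates 2 (adjusted p = 0.0514) and 3 (0.0815) and differentiated replicate 3 (0.0788).

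Among stress and lipid lists, 0 of 18 cholesterol synthesis genes rose and 7 fell, the same adjusted over the list alone (median -0.11, camera adjusted p = 0.00469, adjusted p = 0.208 with an estimated correlation). The median was -0.07 without undifferentiated replicate 1. Sc5d fell by 1.26 and Sqle by 1.14, both enzymes of the sterol pathway. Of 21 genes of the integrated and endoplasmic reticulum stress list 3 rose and 9 fell, the same adjusted over the list alone (median -0.23, camera adjusted p = 0.0106). The call was lost with an estimated correlation (adjusted p = 0.337 with an estimated correlation) and with dim genes left out (adjusted p = 0.0504). Vldlr, a lipoprotein receptor, fell by 2.34 and the chaperone Dnajb9 by 1.18. The serine synthesis enzymes Psat1 and Phgdh rose by 1.18 and 0.76, and Creld2, named after its value was seen, by 0.39.

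In the p53 response list 8 of 17 genes rose and 1 fell, 8 and 2 adjusted over the list alone (median 0.39, camera adjusted p = 0.0683). The list passed with quantile normalization (adjusted p = 0.0414), without undifferentiated replicate 3 (0.0458), without differentiated replicate 1 (0.0498) and by fry (0.00462). Its median was 0.25 without undifferentiated replicate 2. The cell cycle inhibitor Cdkn1a rose by 1.39 and Phlda3 by 1.11, while the kinase Plk2 fell by 1.01. Perp, at -0.33, passed within the list alone and was named after its value was seen.

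Of 22 interferon response genes 1 rose and 1 fell, and 0 and 0 adjusted over the list alone (median 0.08, camera adjusted p = 0.836). That median turned to -0.0286 without differentiated replicate 2 and was at most 0.125 when other arrays were left out. The proteasome subunit Psmb9 rose by 0.40 and Irf9 fell by 0.38, and Mx1 differed by 0.38 (limma adjusted p = 0.12). Psmb9 lost its call without undifferentiated replicates 1 (adjusted p = 0.135), 2 (0.0526) and 3 (0.118) and differentiated replicates 2 (0.129) and 3 (0.136), and with median centring (0.0545) and eBayes without the trend (0.0507). Irf9 lost its call without undifferentiated replicates 1 (adjusted p = 0.06) and 3 (0.0608) and differentiated replicates 2 (0.0544) and 3 (0.0513). Mx1 passed without differentiated replicate 1 (0.52, adjusted p = 0.0457) and differed by 0.24 without differentiated replicate 2.

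Neuropeptides and transmitter receptors went both ways. Of 34 measured genes 7 rose and 8 fell, 7 and 9 adjusted over the list alone. The median was 0.08 and the mean -0.23, and the test pointed down (camera adjusted p = 0.521, fry adjusted p = 0.00599). That median was 0.04 with quantile normalization and 0.03 to 0.09 when each array was left out. P2ry12, a purine receptor, fell by 3.39 ± 0.15 (SE) and Drd2, a dopamine receptor of glomus cells, by 2.57 ± 0.11. Npy1r, a neuropeptide Y receptor, rose by 2.36 ± 0.20 and the neurotrophin Bdnf by 0.59 ± 0.12.

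Of the 24 lists, 7 were called higher and 9 lower, and 2 of these 16 calls held with an estimated correlation. With only 3 arrays per group, precision was limited by the number of arrays, and an exact permutation test of a single value could not go below p = 0.1.

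**Figure D3:**
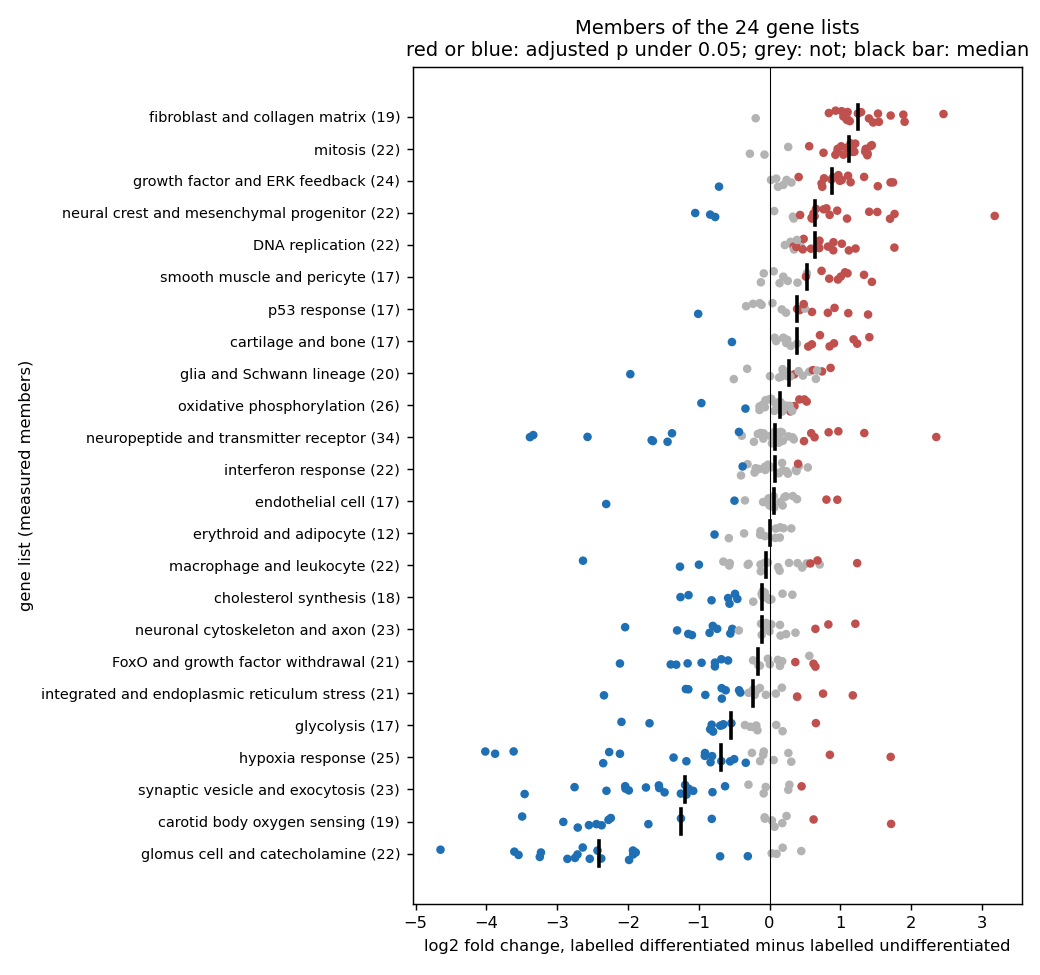
Log2 fold change (horizontal axis, labelled differentiated minus labelled undifferentiated, n = 3 arrays each) of every measured member of the 24 gene lists, ordered by their medians (black bars), with the number of measured members in brackets. Members past an adjusted p of 0.05 are red where they rose and blue where they fell, and medians run from -2.40 for glomus cell genes to 1.25 for collagen matrix genes.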

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

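Probe sets without a single gene symbol stood outside the comparison of named genes. Of 13904 such probe sets, 1943 passed a limma adjusted p of 0.05 between the arrays labelled differentiated and those labelled undifferentiated, 1014 higher and 929 lower, and 163 of them with a log2 change of at least 2. They are listed here because they are a signal in data that the gene-level comparison did not use, and no explanation was tested. Their calls came from a fit of all 29214 probe sets, of which 6018 passed, so the adjustment was not that of the 14506 genes. They were a smaller share than the 29.6% of named genes called. Control probe sets and probe sets with identical values were not removed from that fit.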

How the results depend on the processing

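The alternative without older symbols was chosen after seeing the data. Of 1543 alternative values of 103 named genes, 1485 kept their side of the threshold, 52 lost the call, 6 gained it and 0 called values changed sign (values not called, such as that of Tubb3, could); the unmoderated test accounted for 16 of the losses. The labels do not say whether the replicate numbers pair the arrays, and the values did not settle it. Same-numbered arrays correlated at 0.115, 0.124 and -0.00376 in their deviations from the group means, and own numbers were the best match for 2 of 3. With the replicate block 4430 genes changed and the glia list passed (adjusted p = 0.0271), as did Nes (0.65, adjusted p = 0.000308); no other list call changed under the block. The cause of the changes below was not tested, except that fewer arrays, fewer genes or a stricter threshold were in the alternative itself.

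Counts of changed genes were 1160 (464 higher, 696 lower) with a log2 change of at least 1, 2963 (1356 higher, 1607 lower) at an adjusted p under 0.01, and 2740 (1193 higher) with the unmoderated test. They were 3545 to 4030 when each array was left out, 4473 with quantile normalization and 4082 with median centring, where 51.8% and 45.6% were higher, against 49.7% in the values as deposited. Quantile normalization brought in oxidative phosphorylation (adjusted p = 0.0444) and p53 (0.0414, median 0.43). With dim genes left out, the neuronal cytoskeleton list (0.123) and the stress list (0.0504) were lost, and medians were -1.98 for oxygen sensing, 0.735 for smooth muscle and -0.23 for FoxO. Without older symbols the oxygen sensing median was -1.03.

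With an estimated correlation 14 list calls were lost, with adjusted p of 0.116 for oxygen sensing, 0.337 for neuronal cytoskeleton, 0.189 for progenitors, 0.0897 for smooth muscle, 0.156 for fibroblasts, 0.208 for cartilage, 0.189 for mitosis, 0.202 for DNA replication, 0.215 for hypoxia, 0.32 for glycolysis, 0.156 for growth factor feedback, 0.156 for FoxO, 0.208 for cholesterol and 0.337 for stress. Fry brought in p53 (0.00462) and neuropeptides (0.00599). On ranks, neuronal cytoskeleton was lost (0.0592) and glia gained (0.0233).

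When each array was left out, adjusted p ranged from 0.0135 to 0.0806 for neuronal cytoskeleton, 0.0458 to 0.106 for p53 and 0.00796 to 0.334 for glia. Medians ranged from -1.41 to -1.10 for oxygen sensing, 1.15 to 1.42 for fibroblasts, -0.25 to -0.12 for FoxO, 0.25 to 0.43 for p53, 0.36 to 0.52 for cartilage, -0.33 to -0.20 for stress, -1.29 to -1.12 for synaptic vesicles, 0.53 to 0.69 for smooth muscle, 0.49 to 0.65 for DNA replication and -0.0286 to 0.125 for interferon. Among lists not called, leaving out arrays turned the sign of the macrophage median (-0.13 to 0.08), the erythroid and adipocyte median (-0.05 to 0.06) and the interferon median above, and gave 0.0151 to 0.162 for endothelial cells, 0.09 to 0.22 for oxidative phosphorylation and 0.03 to 0.09 for neuropeptides. How far dim genes stood over background was not known.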

Other observations

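Tests of a single wrong array and of the share of glomus cells were chosen after the results were seen, and the 12 further lists below were gathered after the fixed lists had been examined, with p-values adjusted over those 12. Some members of these lists had already been seen to change, among them Mmp2, Mmp9, Mmp13, Itga6 and Cd74. The same holds for the channels Kcnk3, Kcnk9 and Cacna1h and the carriers Slc18a1 and Slc18a2, which were in the fixed lists. The p-values of the lists that hold them are therefore not independent of the results above. All directions are again those of the arrays labelled differentiated against those labelled undifferentiated. Of 21 matrix metalloproteinases 10 rose and 1, Mmp7, fell by 0.85 (median 0.36, camera adjusted p = 0.000904, adjusted p = 0.213 with an estimated correlation), with Mmp9 and Mmp13 in the lead at 2.87 and 2.62. Of 21 integrins 11 rose and 0 fell (median 0.57, camera adjusted p = 0.000904, adjusted p = 0.255 with an estimated correlation), Itgb3 by 2.16 and Itga2 by 1.51. Among 21 semaphorins and plexins, guidance ligands and their receptors, 9 rose and 3 fell (median 0.42, camera adjusted p = 0.0354, adjusted p = 0.318 with an estimated correlation). Sema7a rose by 2.26 and Sema3d by 2.15, while Sema6b, Sema4f and Sema5a fell by 1.57, 0.69 and 0.52. Of 18 further S phase genes 8 rose and 0 fell (median 0.41, camera adjusted p = 0.00103, adjusted p = 0.119 with an estimated correlation), with Hells at 1.28.

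Of 33 voltage-gated calcium and sodium channel genes 2 rose, 12 fell and the others did not pass (median -0.20, camera adjusted p = 0.000904, adjusted p = 0.119 with an estimated correlation). Cacna2d2 fell by 2.28, Cacna1d by 2.26 and Scn3b by 2.21. Of 83 potassium channel genes 6 rose and 14 fell, with a median of 0.06 (0.05 with quantile normalization, 0.03 with median centring) against a test that pointed down (camera adjusted p = 0.399); the background channels Kcnk9 and Kcnk3 fell by 2.71 and 2.24. Of 10 genes of MHC class II antigen presentation 0 rose and 5 fell (median -0.48, camera adjusted p = 0.00227, adjusted p = 0.318 with an estimated correlation). These were RT1-Da at -3.52, Cd74 at -2.64, RT1-Ba at -1.36, RT1-Db1 at -0.67 and RT1-Bb at -0.62. Of 291 solute carriers 40 rose and 59 fell (median 0.01, and -0.03 and -0.02 with quantile normalization and median centring, camera adjusted p = 0.148), and of 1100 olfactory receptors 26 rose and 1 fell (median 0.11, and 0.02 with quantile normalization and 0.08 with median centring, camera adjusted p = 0.0609). These receptor calls were a far smaller share than the 29.6% of all genes called. Several were dim, such as Or8k16b, with means of 1.65 (labelled undifferentiated) and 2.50 (labelled differentiated). The lower quartiles of the arrays were 3.37 to 3.52, so such changes may lie within background. The genes named in these paragraphs were chosen after their values were seen.

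Arrays labelled differentiated had higher mitosis and growth factor genes and lower glomus and hypoxia genes, the reverse of what mitogen withdrawal and 3% oxygen would be thought to give. The fall of hypoxia genes was uneven: of 25 in the fixed list 16 fell, 2 rose and 7 did not pass. Whether these falls were separate from those of the glomus genes was not tested, so they may not reflect the oxygen level. Against a single wrong label, the lowest correlation within the groups, 0.9857, was above the highest between them, 0.9696. As to a smaller share of glomus cells alone, the fibroblast median exceeded the macrophage median by 1.295. Its 95% bootstrap interval was 0.83 to 1.70, and the difference ran from 1.16 to 1.39 when each array was left out. Both medians were known when this comparison was chosen, so it describes the lists and is no independent test. The bootstrap intervals in this paragraph resampled genes, not arrays. Genes within a list moved together (estimated correlation 0.317 for fibroblasts and 0.639 for macrophages), so the intervals may be too narrow. A candidate explanation is that the labels of the groups were exchanged. Growth factor feedback genes outside the fixed lists had a median of 0.50 (interval 0.30 to 0.89). Of 18, 13 rose and 2 fell (camera adjusted p = 0.000904, adjusted p = 0.255 with an estimated correlation). The 2 falls were Dusp1 at -1.36 and Arc at -0.94, and the rises included Il11 at 1.90 and Errfi1 at 1.36. The rises extend the pattern to more genes of that kind but do not decide for an exchange. General hypoxia genes outside the fixed lists also left it open, with a median of -0.0953 (interval -0.55 to 0.06), 2 of 19 rising and 7 falling (camera adjusted p = 0.0312, adjusted p = 0.318 with an estimated correlation). The 7 falls included Gbe1 at -2.74 and Stc2 at -2.40, and the 2 rises were Rab20 at 0.79 and Wsb1 at 0.51. An exchange and a biological response of correctly labelled cultures, such as growth of mesenchymal cells without mitogens, cannot be told apart here, because no other sample fixes the labels. Mitogens and oxygen changed together, so a response could not be assigned to either of them.

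Cytosolic ribosomal protein genes rose together in the arrays labelled differentiated, 59 of 66 rising and 0 falling, with a median of 0.56 (camera adjusted p = 3.58e-14, adjusted p = 0.318 with an estimated correlation). An intensity-dependent shift was argued against by 10000 random lists of other genes matched on mean expression, whose highest median was 0.273. The ribosomal median was 0.533 with median centring and 0.62 with quantile normalization. Median centring moved the median of all log2 fold changes only from 0.0597 to 0.0306, and quantile normalization only to 0.0309. Both could therefore hardly lower the ribosomal median, and their values say little on the scaling of the arrays. The scaling thus stays open. Biological differences between the cultures stay open and were not tested.

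Of the 10 splits of the 6 arrays into 3 and 3, 1, the real split, gave as many as 4286 changed genes, and the highest of the others gave 0. Every other split mixed arrays of both groups in each part. The difference between the groups then entered the residual spread, so calls were hardly possible there. The contrast with 0 therefore adds no support for the count. With 10 splits a share under 0.05 cannot be reached.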
